A study of Mus musculus with 4 samples.

How the data were processed

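Total RNA of Py2T mouse breast cancer cells grown in DMEM with 10% FCS was measured on Affymetrix expression arrays, 2 from untreated cells and 2 from cells given 2 ng/ml TGFβ for 5 days. Per the labels, RNA was extracted with an RNeasy kit, and 100 ng of total RNA was amplified with the Ambion WT Expression kit and labelled with the Affymetrix WT Terminal Labeling kit. The deposited values are log2 expression values per probe set that the authors made with RMA (background correction, quantile normalization and probe-set summary) in the R package oligo, without a stated version. The probe-set annotation and summary level behind them are not given in the sources used here. All 4 arrays cover the same probe sets, with values between 3.328 and 14.29 and medians within 6.742 to 6.756. No detection calls come with the values, and no genome build is named for the array, so no coordinates are given. The number of arrays limits the precision.

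Probe sets were named from the array's gene table. A probe set was used where the table gives 1 symbol, which holds for 21789, while 1621 list several symbols and 12146 list none. For the 999 genes with several such probe sets, the one with the highest mean over the 4 arrays stood for the gene, and in no gene did 2 probe sets pass in opposite directions. This left 19938 genes. Of 19939 Entrez identifiers 19856 were in the RefSeq table of the mouse genome used for names, and 0 symbols were changed. Probe sets with several symbols or without one are not analysed here as genes. With every probe set tested, 159 of those without a symbol (1.31%) and 45 of those with several (2.78%) passed.

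TGFβ-treated and untreated arrays were compared with limma 3.58.1 in R 4.3.3, by a linear model per gene with empirical Bayes moderation of the variances (moderated, two-sided test, 2 residual and 3.77 prior degrees of freedom). P-values were adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. No values were filtered, transformed or normalized further. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333, so no such test was used for single genes. Errors are standard deviations of 2 arrays or standard errors of the fitted difference, and intervals are 95% intervals of the fit.

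Gene lists, 27 in number with 661 distinct genes of which 616 were measured, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. For each list the members called higher, lower or neither are given, along with the calls when p-values are adjusted over the list alone. Camera was repeated with a correlation estimated per list, which also limits its test to the 2 residual degrees of freedom, so few lists could pass. Fry was run as a test that does not compare a list with other genes. Some list genes are not reported here.

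The comparison, the tests, the lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where the text says otherwise. The rule names the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap and whose brighter group has a mean of at least 7, leaving out predicted genes and olfactory, vomeronasal and small RNA genes. It adds genes set in advance (among them Tead1 to Tead4, Yap1, Wwtr1, Zyx, Cdh1, Epcam, Cdh2, Vim, Fn1, Snai1, Snai2, Zeb1, Zeb2, Twist1, Ccn1, Ccn2, Ankrd1 and Smad7), whatever their values. It also adds, for each list that passed or has at least 3 called members, up to 3 called members with the largest rise and up to 3 with the largest fall. This named 129 genes, and 41 more were named after their values were seen. Members given as examples of genes that were not called, such as Cldn4, Jup, F11r, Acta2 and Tagln, were also picked afterwards.

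Alternatives were median centring, cyclic loess, repeated quantile normalization, leaving out the dimmest 25% or the dimmer 50% of genes, the mean of all probe sets of a gene, an intensity trend with robust variances, the replicate number as a block, a 2-fold threshold, limma's treat against a log2 difference of 0.5, all probe sets by identifier, and leaving out each array in turn. A crossed pairing and 8 further gene lists were chosen after seeing the data. Camera p-values of these further lists were adjusted over the 8 alone, apart from the lists fixed in advance. The procedure was tested on simulated data in which 200 of 19938 genes were changed, in 10 simulations. At log2 differences of 0.5, 1 and 2 it recovered 76.7%, 99.6% and 100% of them, with 22.7 false calls per simulation on average. Even with all 200 changed genes called, this is a larger share of calls than the adjusted p threshold of 0.05 aims at. The threshold was therefore not held in these simulations, and the calls in the data may include more false ones than it implies. A list shifted by 0.3, mitosis, was called in 10 of 10 simulations, with 1 call of another list over all of them. Genes were simulated independently, while the estimated correlation of the mitosis list was 0.91 in the data. The simulations therefore do not give the rate of false list calls for correlated lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.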

Results

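RNA from Py2T cells, a mouse breast cancer cell line that undergoes an epithelial to mesenchymal transition (EMT) under TGFβ, was measured on 4 Affymetrix arrays. The 2 untreated arrays and the 2 arrays from cells given 2 ng/ml TGFβ for 5 days form the 2 groups. Of the probe sets on the array 21789 carry 1 gene symbol, and values are on the RMA log2 scale, with medians over all probe sets of 6.756 and 6.742 in the untreated arrays and 6.756 and 6.744 in the TGFβ arrays. The number of arrays limits the precision of every value below.

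TGFβ-treated and untreated cells were compared to ask which genes change during TGFβ-induced EMT, in a study whose title names Tead2, Yap/Taz and zyxin. Cdh6, a type II cadherin of cell contacts, rose to 11.46 ± 0.05 (log2 mean ± SD, n = 2) from an untreated mean near background, a measured difference of 44.1-fold or 5.46 ± 0.09 (SE) on the log2 scale. Il11, a secreted cytokine that signals through gp130, rose 37.5-fold, from 6.49 ± 0.14 to 11.71 ± 0.29. Of 39 epithelial junction genes 26 fell and 13 did not pass, among them the tight junction gene Ocln (-3.07 on the log2 scale, to near background) and the small GTPase Rab25 (-2.94). That list was called lower with camera (adjusted p = 9.6e-17), a call lost at adjusted p = 0.588 with an estimated correlation. The transcription factor Tead2 rose 3.12-fold and the EMT regulators Zeb1 and Zeb2 rose 3.23-fold and 2.61-fold. Of 20 cholesterol synthesis genes 12 fell, 0 rose and 8 did not pass (camera adjusted p = 5.7e-11, and adjusted p = 0.588 with an estimated correlation).

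Of 19938 genes tested with limma, 2720 (13.6%) passed at an adjusted p under 0.05, 1294 of them higher and 1426 lower after TGFβ. At least a 2-fold difference was seen for 323 of the higher and 354 of the lower genes, and at least a 4-fold difference for 68 and 78. For every called gene both TGFβ arrays lay beyond both untreated arrays. The number of calls was 1535 without untreated replicate 1, 1764 without untreated replicate 2, 1811 without TGFβ replicate 1 and 2260 without TGFβ replicate 2, with the lone array assumed to vary like the other group. The labels call the samples biological replicates and say no more of how the cultures were kept, so the p-values measure the spread between these samples.

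Among the other large rises, the membrane carboxypeptidase Cpm rose 17.8-fold and Cdh10, another type II cadherin, rose 15.3-fold. Hmgcll1, related to the ketogenic enzyme HMG-CoA lyase, rose 15.7-fold and Penk, the precursor of enkephalin peptides, rose 15.2-fold. Ccn4, a matricellular protein also called Wisp1, rose 13.6-fold, the small GTPase Rab15 12.8-fold and the diacylglycerol kinase Dgkk 12.1-fold. The late cornified envelope gene Lce1h rose 12.7-fold, from 8.92 ± 0.54 to 12.59 ± 0.29, with near-identical neighbours in the genome that its probes may not separate. Cdh6, Il11, Hmgcll1, Cpm, Cdh10, Penk, Ccn4 and Rab15 had untreated means under 7, close to the bottom of the array's range, where background limits their folds and their order. The same limit holds for the sizes given below for Ocln, Ap1m2, Krt20, Tpm2, Wnt11, Itgb6, Rbms3, Lmo7, Mmp12, Pfkfb3, Cxcl5, Tap1, Foxa1, Tgm5 and Lce1f, each with a group mean under 7, and for the uncalled Acta2, Tagln and Lor.

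Csf2rb2, a beta subunit of the interleukin 3 receptor, fell from 10.53 ± 0.27 to 6.64 ± 0.04, or 14.7-fold. Its sequence is close to that of Csf2rb, so the probe set may read both. Fst, the secreted activin antagonist follistatin, was 14.0-fold lower and Mal2, a protein of apical transport in epithelial cells, was 13.2-fold lower. The epoxide hydrolase Ephx1 was 11.5-fold lower, the actin-binding adaptor Sorbs2 10.7-fold lower and the ectoenzyme Bst1 10.6-fold lower. Klk10, a secreted kallikrein peptidase, was 9.74-fold lower, the integrin subunit Itga8 9.38-fold lower and the proliferin Prl2c5, one of several near-identical genes, 9.08-fold lower. The chemokine Ppbp was 8.72-fold lower, from 11.18 ± 0.91 to 8.06 ± 0.56 (adjusted p = 0.0097). With an intensity trend and robust variances its adjusted p was 0.056. Csf2rb2, Mal2, Sorbs2, Bst1 and Itga8 had TGFβ means under 7, so background limits their folds and their order.

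Of the TEAD factors, which bind DNA for the coactivators Yap and Taz, Tead2 rose from 9.66 ± 0.24 to 11.30 ± 0.12 (log2 mean ± SD, n = 2), a log2 difference of 1.64 ± 0.13 (SE, adjusted p = 0.0016). Tead3 fell by 0.41 (adjusted p = 0.027) and Tead4 fell by 0.39 (adjusted p = 0.032) on the log2 scale. The Tead3 call was lost without untreated replicate 1 (-0.42, adjusted p = 0.11), untreated replicate 2 (-0.40, adjusted p = 0.12) or TGFβ replicate 2 (-0.34, adjusted p = 0.085). The Tead4 call was lost without any of the 4 arrays, with adjusted p of 0.069 and 0.16 without untreated replicates 1 and 2 and 0.080 and 0.10 without TGFβ replicates 1 and 2, and after median centring of the arrays (adjusted p = 0.0502). Tead1 differed by -0.36 (adjusted p = 0.086) and passed after repeated quantile normalization (-0.37, adjusted p = 0.0499) or without TGFβ replicate 1 (-0.49, adjusted p = 0.042). Yap1 differed by 0.09 (95% interval -0.09 to 0.28) and Wwtr1, which encodes Taz, by 0.39 (95% interval 0.12 to 0.67, adjusted p = 0.079). Wwtr1 passed without TGFβ replicate 2, at 0.53 (adjusted p = 0.037).

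Zyx, which encodes the focal adhesion and actin filament protein zyxin, rose 1.69-fold, from 10.92 ± 0.16 to 11.68 ± 0.29 (adjusted p = 0.030). With the replicate number as a block its adjusted p in limma was 0.087. Its call was lost without untreated replicate 1 (0.64, adjusted p = 0.12) or TGFβ replicate 1 (0.55, adjusted p = 0.063). Of 3 genes often read as Yap and Taz targets, Ccn2, a matricellular protein, rose by 0.88 on the log2 scale (adjusted p = 0.0016). Ccn2 is also a member of the list of direct TGFβ and Smad targets, so its rise cannot be assigned to Yap and Taz. Ccn1 differed by 0.45 (adjusted p = 0.15) and passed without untreated replicate 2, at 0.70 (adjusted p = 0.023), while Ankrd1 differed by 0.22 (adjusted p = 0.20).

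**Figure D1:**
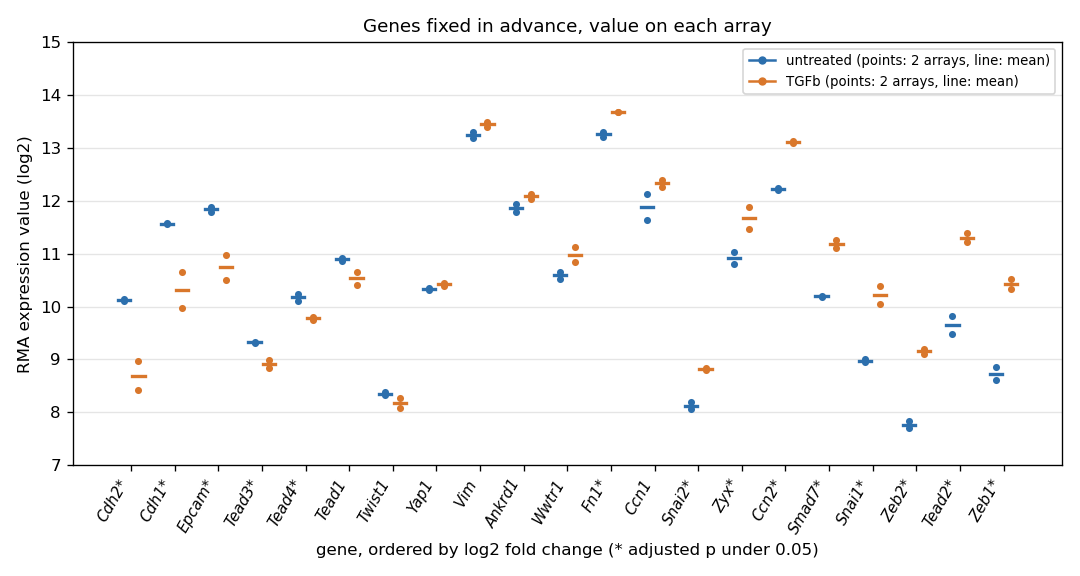
Expression (RMA log2, vertical axis) of the 21 measured genes fixed in advance, ordered by log2 fold change along the horizontal axis, with a point per array and a line at the mean of the 2 untreated (blue) and 2 TGFβ (orange) arrays. Tead2, Zeb1, Zeb2 and Snai1 had the largest rises, and Cdh2, Cdh1 and Epcam the largest falls.

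Epithelial junction and polarity genes were called lower with camera (adjusted p = 9.6e-17, and adjusted p = 0.588 with an estimated correlation). Of 39 measured members 0 rose, 26 fell and 13 did not pass, against 0 and 28 adjusted over the list alone, with a median log2 difference of -0.95. Rab25, which acts in apical recycling, fell by 2.94 and the clathrin adaptor subunit Ap1m2 fell by 2.71 on the log2 scale. The claudins Cldn1 (-2.22) and Cldn7 (-2.18), the epithelial transcription factor Grhl2 (-1.60) and the splicing factor Esrp1 (-1.41) also fell. E-cadherin, Cdh1, fell from 11.57 ± 0.02 to 10.31 ± 0.49 (adjusted p = 0.017) and was not called without untreated replicate 1 (-1.24, adjusted p = 0.057). The adhesion gene Epcam fell by 1.10 (adjusted p = 0.0094), while Cldn4 differed by 0.21, Jup by 0.15 and F11r by 0.01 without passing. The mean difference of the list was -1.24 in TGFβ replicate 1 and -0.941 in TGFβ replicate 2.

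Keratins, the intermediate filaments of epithelia, were mostly not called. Of 13 measured keratins 1 rose, 1 fell and 11 did not pass, against 1 and 1 adjusted over the list alone (median -0.04, camera adjusted p = 0.50). The median was -0.073 and -0.067 without untreated replicates 1 and 2, and -0.062 and -0.083 without TGFβ replicates 1 and 2. The luminal keratins Krt8, Krt18 and Krt7 differed by 0.06, -0.11 and -0.14, with means near the top of the array's range, where differences may be compressed. Krt5, Krt6a, Krt6b, Krt15, Krt19, Krt20 and Krt23 had both means under 7, so a change in them would be hard to detect. The basal keratin Krt14 fell by 1.38 (adjusted p = 0.043), a call lost with an intensity trend and robust variances (adjusted p = 0.11), without untreated replicate 2 (-1.03, adjusted p = 0.12) or without TGFβ replicate 2 (-0.99, adjusted p = 0.0995). Krt20, chosen after its values were seen and dim in both groups, rose by 0.44. Its call was lost without untreated replicate 1 (adjusted p = 0.095), untreated replicate 2 (adjusted p = 0.14) or TGFβ replicate 2 (adjusted p = 0.096).

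Mesenchymal and contractile genes went both ways, with more rises than falls. Of 28 measured members 8 rose, 3 fell and 17 did not pass, against 11 and 3 adjusted over the list alone. The median was 0.23 and camera called the list higher (adjusted p = 5.1e-04, and adjusted p = 0.588 with an estimated correlation). Without untreated replicate 1 the median was 0.14. Itga5, the alpha subunit of the fibronectin receptor, rose 4.36-fold and the adhesion molecule Ncam1 4.26-fold. Fn1, fibronectin itself, rose from 13.25 to 13.67 (adjusted p = 0.020), near the top of the array's range, a call lost without any of the 4 arrays. Its adjusted p was 0.063 and 0.11 without untreated replicates 1 and 2, and 0.068 and 0.057 without TGFβ replicates 1 and 2. Mcam, an adhesion molecule, rose by 1.92 with a TGFβ SD of 1.01, and by 1.20 without TGFβ replicate 1. Its call (adjusted p = 0.039) was lost without untreated replicate 1 (adjusted p = 0.11) or 2 (adjusted p = 0.092) and with an intensity trend and robust variances (adjusted p = 0.12). The 3 members that fell were N-cadherin, Cdh2 (-1.42), the calcium-binding protein S100a4 (-1.09), and the tropomyosin Tpm2 (-0.95). The intermediate filament gene Vim, also near the top of the range at 13.25 in untreated cells, differed by 0.19 (adjusted p = 0.21), and the smooth muscle genes Acta2 and Tagln by 0.26 and 0.20.

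EMT transcription factors showed 6 rises, 2 falls and 14 genes that did not pass among 22 measured, against 9 and 3 adjusted over the list alone. Zeb1, a repressor of Cdh1, rose from 8.73 to 10.43 (adjusted p = 8.7e-04) and Zeb2 from 7.77 to 9.16 (adjusted p = 7.0e-04). Snai1 rose by 1.24 (adjusted p = 0.0028) and Snai2 by 0.70 (adjusted p = 0.0050), while Twist1 differed by -0.18 (adjusted p = 0.30). Klf4, a factor that maintains epithelial identity, fell by 1.02, and the forkhead factor Foxc1 fell by 0.61, a call lost without untreated replicate 1 (-0.54, adjusted p = 0.061). The list median was 0.09 and camera called it higher at adjusted p = 0.030, against adjusted p = 0.588 with an estimated correlation. That call was lost without TGFβ replicate 2 (median 0.14, adjusted p = 0.080) and without the dimmer 50% of genes (median 0.08, adjusted p = 0.19). The median was 0.16 without untreated replicate 1 and 0.17 without TGFβ replicate 1.

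Direct targets of TGFβ and Smad signalling were called higher with camera (adjusted p = 9.8e-06, and adjusted p = 0.588 with an estimated correlation). Of 23 measured members 12 rose, 2 fell and 9 did not pass, with the same counts of 12 and 2 adjusted over the list alone. The median was 0.43. The NADPH oxidase Nox4 rose 7.23-fold, the ligand Wnt11 2.78-fold and Smad7, the inhibitory Smad of the pathway, 1.99-fold (adjusted p = 0.0018). The 2 members that fell were Itgb6, an integrin subunit that activates latent TGFβ (-2.64), and the type I receptor Tgfbr1 (-0.58). The Tgfbr1 call was lost without untreated replicate 1 (adjusted p = 0.099), TGFβ replicate 1 (adjusted p = 0.12) or TGFβ replicate 2 (adjusted p = 0.081).

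TGFβ and BMP ligands, receptors and Smads moved in both directions. Of 35 measured members 9 rose, 5 fell and 21 did not pass, against 10 and 7 adjusted over the list alone. Fstl3, a secreted activin inhibitor, rose 6.86-fold, the activin subunit Inhba 1.98-fold and the receptor Acvr1 1.55-fold. Its relative Fst fell by 3.81, the ligand Bmp4 fell by 2.46 and the type II receptor Tgfbr2 fell by 0.95. The list was not called (adjusted p = 0.60), and its median of -0.0018 and mean of -0.042 were negative where camera's direction was up. Of the 4 Id genes, dominant negative helix-loop-helix factors induced by BMP signalling, 0 rose, 2 fell and 2 did not pass, against 1 and 3 adjusted over the list alone. Id3 fell by 1.19 (adjusted p = 8.3e-04) and Id1 fell by 0.80 (adjusted p = 0.011), both chosen after their values were seen. The Id median was -0.60 (camera adjusted p = 0.061), and the list passed with median centring (-0.58, adjusted p = 0.044), cyclic loess (-0.59, adjusted p = 0.048), without untreated replicate 1 (-0.65, adjusted p = 0.035) and without TGFβ replicate 2 (-0.59, adjusted p = 0.040). It did not pass without untreated replicate 2 (-0.54, adjusted p = 0.15) or TGFβ replicate 1 (-0.60, adjusted p = 0.055).

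Hippo pathway components, the kinases and scaffolds upstream of Yap and Taz together with the TEAD factors, showed 5 rises, 7 falls and 23 genes that did not pass among 35 measured. Adjusted over the list alone the counts were 7 and 8 (median 0.08, camera adjusted p = 0.50). Tead2 had the largest rise, ahead of the giant cadherin Fat4, at 2.87-fold, and the LIM protein Wtip, at 1.71-fold. The cadherin Fat1 fell by 0.56, a call lost without untreated replicate 1 (adjusted p = 0.059) or 2 (adjusted p = 0.075). Among 22 measured Yap and Taz target genes 8 rose, 2 fell and 12 did not pass, against 8 and 3 adjusted over the list alone. The ectoenzyme Nt5e rose 3.43-fold and the RNA-binding protein Rbms3 2.94-fold, while the BMP-binding membrane protein Crim1 (-0.55) and the phosphatase Ptpn14, a Yap inhibitor (-0.41), fell. The Ptpn14 call was lost without untreated replicate 1 (adjusted p = 0.089), untreated replicate 2 (adjusted p = 0.10) or TGFβ replicate 2 (adjusted p = 0.071). The target list, with median 0.11, was not called (camera adjusted p = 0.099), and it passed without untreated replicate 1 (median 0.12, adjusted p = 0.017) and without TGFβ replicate 2 (median 0.21, adjusted p = 0.040). Its median was 0.061 without untreated replicate 2 (adjusted p = 0.062) and 0.039 without TGFβ replicate 1 (adjusted p = 0.17).

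Focal adhesion and LIM proteins, the family of zyxin, showed 9 rises, 6 falls and 22 genes that did not pass among 37 measured, against 13 and 6 adjusted over the list alone. The actin-linking tensin Tns1 rose 5.71-fold, the filamin Flnc 3.21-fold and the actin-binding LIM protein Pdlim1 3.13-fold. Another tensin, Tns2 (-1.19), the vinculin-binding adaptor Sorbs3 (-0.83) and the LIM protein Lmo7 (-0.80) fell. The median was 0.16 and camera called the list higher (adjusted p = 0.017, and adjusted p = 0.827 with an estimated correlation). Without TGFβ replicate 1 the median was 0.091 and the call was lost (adjusted p = 0.077). Integrins, the matrix receptors of these adhesions, showed 4 rises, 7 falls and 9 genes that did not pass among 20 measured, with 4 and 7 adjusted over the list alone (median -0.05, camera adjusted p = 0.40). The integrin median was -0.078 and -0.041 without untreated replicates 1 and 2, and 0.0038 and -0.11 without TGFβ replicates 1 and 2. Itgb3, the beta subunit of the vitronectin receptor, rose 10.6-fold, and Itgb1, the partner of Itga5, rose 1.76-fold. Itgb4, the hemidesmosome subunit, fell by 1.41.

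Proteases and their inhibitors showed 12 rises, 2 falls and 15 genes that did not pass among 29 measured, against 13 and 4 adjusted over the list alone. The median was 0.27 and camera called the list higher (adjusted p = 0.011, and adjusted p = 0.588 with an estimated correlation). That call was lost without the dimmer 50% of genes, where the median was 0.54 (adjusted p = 0.089). The metalloproteinase inhibitor Timp3 rose 6.11-fold, and the macrophage elastase gene Mmp12 rose 8.40-fold from an untreated mean of 6.02, near background. The collagenase Mmp13 rose from 8.26 ± 0.70 to 11.35 ± 1.47 (adjusted p = 0.037), and by 2.06 in place of 3.09 without TGFβ replicate 2. Its call was lost without untreated replicate 1 (3.59, adjusted p = 0.0502), without untreated replicate 2 (2.60, adjusted p = 0.11) and with an intensity trend and robust variances (adjusted p = 0.24). The 2 members that fell were Klk10 and the membrane metalloproteinase Adam8, which fell by 0.93, a call lost without untreated replicate 2 (adjusted p = 0.062) or TGFβ replicate 2 (adjusted p = 0.061). Collagens and matrix genes showed 11 rises, 6 falls and 26 genes that did not pass among 43 measured, against 13 and 6 adjusted over the list alone (median 0.06, camera adjusted p = 0.22). The matrix median was -0.0090 and 0.080 without untreated replicates 1 and 2, and 0.077 and 0.028 without TGFβ replicates 1 and 2. The collagen lysyl hydroxylase Plod2 rose 3.57-fold and the proteoglycan Vcan 2.22-fold, while Lama5, a laminin chain of basement membranes, fell by 1.36.

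Cholesterol synthesis genes were lower, with 0 rises, 12 falls and 8 genes that did not pass among 20 measured, against 0 and 19 adjusted over the list alone. The median was -0.70 and camera called the list lower (adjusted p = 5.7e-11, and adjusted p = 0.588 with an estimated correlation). Without TGFβ replicate 1 the median was -0.43. Lanosterol synthase, Lss, fell by 1.48, the isoprenoid enzyme Idi1 fell by 1.45 and the early pathway enzyme Hmgcs1 fell by 1.10. The TGFβ replicates differed in this list, with a mean difference from untreated cells of -0.979 in replicate 1 and -0.519 in replicate 2.

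Glycolysis and hypoxia genes went both ways, with 5 rises, 7 falls and 11 genes that did not pass among 23 measured, against 6 and 8 adjusted over the list alone (median -0.14, camera adjusted p = 0.14). The angiogenic factor Vegfa rose 2.78-fold, the glycolytic regulator Pfkfb3 2.62-fold and the hexokinase Hk2 2.09-fold. The aldolase Aldoc (-2.48), the carbonic anhydrase Car9 (-1.77) and the mitophagy protein Bnip3 (-1.48) fell. Amino acid stress genes showed 3 rises, 1 fall and 18 genes that did not pass among 22 measured, with 3 and 1 adjusted over the list alone (median 0.10, camera adjusted p = 0.26). The list was called higher without TGFβ replicate 1 (0.28, adjusted p = 0.0036) and lay at -0.023 without TGFβ replicate 2 (adjusted p = 0.86). It did not pass without untreated replicate 1 (0.13, adjusted p = 0.42) or 2 (0.16, adjusted p = 0.13). The stress protein Sesn2 fell by 0.68. The mitochondrial folate enzyme Mthfd2 rose by 0.93, a call lost without TGFβ replicate 1 (adjusted p = 0.0895) or 2 (adjusted p = 0.099), and its difference was 0.62 without untreated replicate 1. The serine synthesis enzyme Psph rose by 0.57 and was not called without untreated replicate 1 (adjusted p = 0.072). The transcription factor Atf5 rose by 0.36, a call lost without any of the 4 arrays (adjusted p = 0.16 and 0.18 without untreated replicates 1 and 2, 0.052 and 0.14 without TGFβ replicates 1 and 2), with cyclic loess (adjusted p = 0.054) and with an intensity trend and robust variances (adjusted p = 0.072). Of 23 measured ribosomal protein genes 0 rose, 0 fell and 23 did not pass with limma, with 0 and 0 adjusted over the list alone and 2 at an unadjusted p under 0.05. Their median was -0.05 (camera adjusted p = 0.13), and the list passed with cyclic loess (median -0.076, adjusted p = 0.031).

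Of 29 measured mitosis genes 0 rose, 4 fell and 25 did not pass, with 0 and 4 adjusted over the list alone. The median was -0.15 and camera called the list lower (adjusted p = 9.6e-04, and adjusted p = 0.827 with an estimated correlation). The list mean was 10.76 and 10.94 in untreated replicates 1 and 2, and 10.75 and 10.56 in TGFβ replicates 1 and 2. Replicates of a condition thus differed (0.174 untreated, -0.184 TGFβ) about as much as the conditions did (mean -0.196). The spindle protein Nusap1 fell by 0.69 and the cytokinesis protein Anln fell by 0.56. The list's call was lost without untreated replicate 2 (-0.056, adjusted p = 0.14) or TGFβ replicate 2 (-0.053, adjusted p = 0.14), and the median was -0.24 without untreated replicate 1 and -0.26 without TGFβ replicate 1. In the DNA replication list the gaps between replicates (0.276 untreated, -0.271 TGFβ) exceeded the mean difference between conditions (-0.091). DNA replication genes showed 1 rise, 2 falls and 26 genes that did not pass among 29 measured, with 1 and 2 adjusted over the list alone (median -0.14, camera adjusted p = 0.087). This list passed without untreated replicate 1 (-0.25, adjusted p = 3.1e-04) and without TGFβ replicate 1 (-0.25, adjusted p = 4.6e-04). Its median was -0.036 without untreated replicate 2 (adjusted p = 0.99) and -0.024 without TGFβ replicate 2 (adjusted p = 0.86). Cyclin E1, Ccne1, rose by 1.03, a call lost without untreated replicate 1 (adjusted p = 0.063) or TGFβ replicate 1 (adjusted p = 0.093). Cell cycle inhibitors and D cyclins showed 1 rise, 2 falls and 10 genes that did not pass among 13 measured, against 3 and 5 adjusted over the list alone (median -0.03, camera adjusted p = 0.60). The median was 0.075 without untreated replicate 1, -0.15 without untreated replicate 2, -0.14 without TGFβ replicate 1 and 0.067 without TGFβ replicate 2. The kinase inhibitor Cdkn2c fell by 0.97. The phosphatase Cdc25a rose by 0.57, a call lost without untreated replicate 1 (adjusted p = 0.14) or TGFβ replicate 1 (adjusted p = 0.12). Cyclin D1, Ccnd1, fell by 0.37, a call lost without any of the 4 arrays, with adjusted p of 0.13 and 0.11 without untreated replicates 1 and 2 and 0.079 and 0.072 without TGFβ replicates 1 and 2.

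Cytokines and chemokines showed 3 rises, 4 falls and 16 genes that did not pass among 23 measured, against 3 and 7 adjusted over the list alone. Besides Il11, the colony-stimulating factor Csf2 rose 5.11-fold and the chemokine Cxcl12 2.19-fold, while the neutrophil chemokine Cxcl5 fell by 2.51 and the cytokine Il24 fell by 1.04. The list was not called (adjusted p = 0.56), with a median of -0.046, a mean of 0.114 and camera's direction down. Interferon response genes showed 1 rise, 2 falls and 23 genes that did not pass among 26 measured, with 1 and 2 adjusted over the list alone (median -0.06, camera adjusted p = 0.49). Oasl2, related to the antiviral oligoadenylate synthetases, rose 3.14-fold and the peptide transporter Tap1 fell by 0.63. The RNA sensor Ddx58 fell by 0.75, a call lost without TGFβ replicate 1 (adjusted p = 0.0501). The interferon list was called lower without TGFβ replicate 2 (-0.22, adjusted p = 0.0017) and its median was 0.037 without TGFβ replicate 1 (adjusted p = 0.17). It did not pass without untreated replicate 1 (-0.074, adjusted p = 0.91) or 2 (-0.087, adjusted p = 0.23).

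Luminal mammary markers showed 3 rises, 4 falls and 12 genes that did not pass among 19 measured, with 3 and 4 adjusted over the list alone. The retinaldehyde dehydrogenase Aldh1a3 rose 5.71-fold and the milk protein Csn3 4.06-fold, while the luminal transcription factors Gata3 (-1.04) and Foxa1 (-0.81) fell. The list was not called (adjusted p = 0.75), with a median of -0.028, a mean of 0.075 and camera's direction down. Basal mammary markers showed 2 rises, 4 falls and 11 genes that did not pass among 17 measured, against 4 and 4 adjusted over the list alone. The growth factor receptor Egfr rose 2.07-fold and the stem cell marker Procr 1.92-fold, while the Notch ligands Jag2 (-1.76) and Dll1 (-1.14) fell. The basal list was not called (adjusted p = 0.87), with a median of 0.0089, a mean of -0.14 and camera's direction down.

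Markers of other cell types that a culture from a tumour could hold were mostly not called. The immune, endothelial and adipocyte list means lay between 6.01 and 6.31 in every array, near background. A change in members at this level would be hard to detect. Of 18 measured immune cell markers 1 rose, 0 fell and 17 did not pass, with 0 and 0 adjusted over the list alone. The member that rose was Cd14, also a luminal marker here, by 0.42. The Cd14 call was lost without untreated replicate 1 (adjusted p = 0.057) or 2 (adjusted p = 0.17) and without TGFβ replicate 1 (adjusted p = 0.073) or 2 (adjusted p = 0.12). The immune list had a median of 0.0078, a mean of -0.069 and camera's direction down (adjusted p = 0.87). Of 15 measured endothelial markers 0 rose, 0 fell and 15 did not pass with limma, with 0 and 0 adjusted over the list alone and 1 at an unadjusted p under 0.05 (median 0.04, camera adjusted p = 0.60). Of 12 measured adipocyte markers 0 rose, 1 fell and 11 did not pass, with 0 and 1 adjusted over the list alone. The lipase Lipe, chosen after its values were seen, fell by 0.92, a call lost without untreated replicate 1 (adjusted p = 0.077) or 2 (adjusted p = 0.054). The adipocyte list had a median of 0.0003, a mean of -0.0083 and camera's direction up (adjusted p = 0.85).

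**Figure D2:**
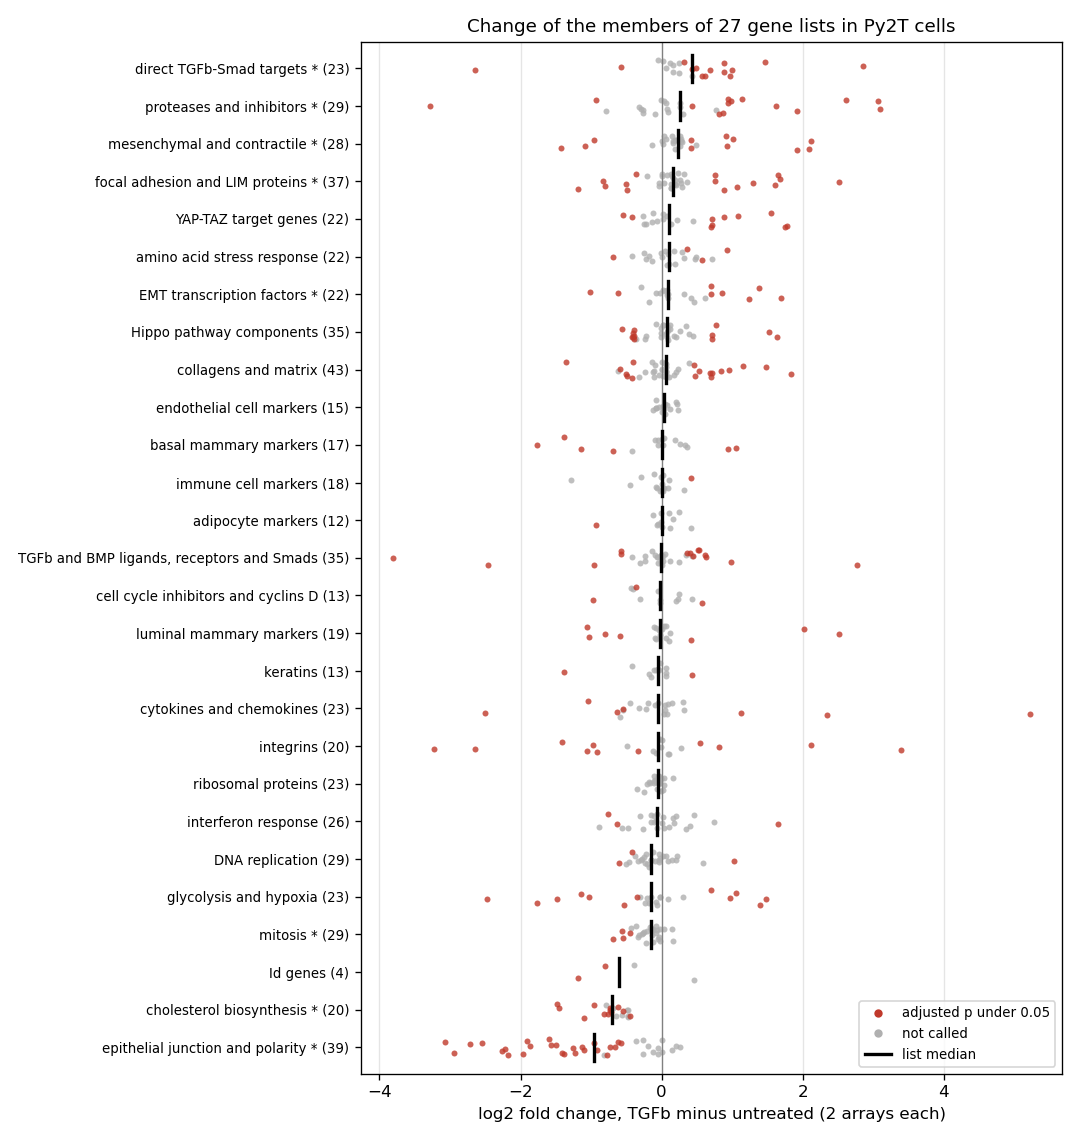
Log2 fold change after TGFβ (horizontal axis) of every measured member of the 27 gene lists (vertical axis), with a point per gene, coloured where the gene passed, and a bar at each list's median. Epithelial junction genes had a median of -0.95 and cholesterol synthesis genes of -0.70, and direct TGFβ and Smad targets had a median of 0.43.

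Over the 27 lists, 8 passed with camera at its preset correlation of 0.01, 5 of them higher and 3 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.588, 0 lists at an unadjusted p under 0.05). That run rests on only 2 residual degrees of freedom, so a lost call need not come from correlation between members. EMT transcription factors, with an estimated correlation of -0.0021, had a camera p of 0.0089 at the preset correlation and of 0.10 with the estimate. The other called lists had higher estimates, 0.91 for mitosis, 0.90 for cholesterol synthesis and 0.37 for epithelial junction genes. Estimates were 0.26 for focal adhesion, 0.19 for mesenchymal, 0.084 for direct target and 0.049 for protease genes. Where the estimate is high, correlation between members may itself account for the lost call. With fry, which asks whether a list's genes move on balance one way, 0 passed (lowest adjusted p = 0.062, 12 lists at an unadjusted p under 0.05). Fry's test of change in either direction called 22 lists.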

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

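The replicate block, treat, all probe sets and the runs without an array are alternatives chosen in advance, and the tests with crossed pairing were chosen after seeing the data. With normalization, dim-gene filters, the mean of probe sets or trend and robust variances, 2454 to 2877 genes passed, against 2720. The 2-fold threshold gave 677 (323 higher, 354 lower) and treat at 0.5 gave 543 (266 and 277), both stricter by construction. All probe sets by identifier gave 1536 (722 and 814), and the cause was not tested. Without 1 array, which leaves fewer samples, 1535 to 2260 genes passed, 740 to 1167 higher and 751 to 1093 lower. The labels do not say that equal replicate numbers pair the samples, and deviations of same-numbered arrays correlate at r = -0.213 across genes, which are not independent replicates. With a replicate block 1624 passed (785 higher, 839 lower), with the same differences and fewer residual degrees of freedom, and with crossed pairing 3640 passed. Under the replicate block 28 named genes lost their call, among them Tead3, Tead4, Zyx, Fn1, Mcam, Mmp13, Krt14 and Fat1, and 1, Ivl, gained it. Apart from Zyx, these changes are not repeated with the single genes above. Over 13 settings 53% to 100% of the 2720 genes were called again, 0 of them with the opposite sign, and 42.0% to 51.6% of calls were higher, against 47.6%. For 170 named genes and 2198 further values the call was the same in 2054, lost in 132, gained in 12 and of opposite sign in 0. Of the 27 lists 0 passed with an estimated correlation and 0 with fry (12 at an unadjusted p under 0.05), both in limma, and 6 to 11 elsewhere, against 8. Some lists that were not called changed camera's direction, and the cause was not tested. Medians without the dimmer 50% of genes were -0.09505 for cytokines, 0.09057 for luminal, -0.1247 for endothelial and -0.3369 for adipocyte markers, and the luminal median was 0.0168 without the dimmest 25%. Fry, which leaves medians as they are, gave another direction than camera for cytokines (-0.04617), luminal (-0.02778) and immune markers (0.007825). Without 1 array in turn, medians ran from 0.03969 to 0.09767 for Hippo components, from -0.2203 to 0.03718 for interferon response, from -0.0871 to -0.01806 for cytokines and from -0.02312 to 0.2844 for amino acid stress. They ran from -0.06104 to 0.005686 for luminal, from -0.03308 to 0.03879 for basal, from -0.02725 to 0.08345 for endothelial and from -0.01675 to 0.05105 for adipocyte markers. Medians also changed sign without 1 array for TGFβ and BMP components (-6.472e-05 to 0.03834) and immune markers (-0.02002 to 0.01973). Signal over background limits dim genes, and 229 called genes had both means under 7.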

Other observations

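The gene lists in this part and the tests of Lce1 cross-hybridization, of other cornified envelope genes, of variation between cultures and of a single share of untreated-like cells were chosen only after the result was seen, as were most genes named here. Genes of xenobiotic metabolism, a list made after the fall of Ephx1 was seen, showed 2 rises, 7 falls and 22 genes that did not pass among 31 measured (median -0.0839, camera adjusted p = 0.0225, and adjusted p = 0.359 with an estimated correlation). Ephx1 itself is counted among the falls, so the camera result partly restates what prompted the list. The aldehyde dehydrogenase Aldh3a1 fell by 2.79, the glutathione transferase Gsta4 fell by 2.37, the cytochrome Cyp1b1 fell by 2.32 and Ahr, the receptor that induces Cyp1b1 and Aldh3a1, fell by 0.84 on the log2 scale. Other list members often read as Ahr targets did not pass. Tiparp, a bright gene, differed by 0.11 (adjusted p = 0.64), Nqo1 by 0.03, Cyp1a1 by -0.16 and Ahrr by -0.27. Nqo1, Cyp1a1 and Ahrr had both means under 7, so a change in them would be hard to detect. Whether the fall of Ahr led to those of Cyp1b1 and Aldh3a1 was not tested. Heme oxygenase, Hmox1, rose 2.30-fold, and Srxn1, which repairs oxidized peroxiredoxins, rose by 0.55. The Srxn1 call was lost without untreated replicate 1 (adjusted p = 0.081), TGFβ replicate 1 (adjusted p = 0.059) or TGFβ replicate 2 (adjusted p = 0.065). Fatty acid synthesis genes showed 1 rise, 6 falls and 14 genes that did not pass among 21 measured (adjusted p = 0.00335, and adjusted p = 0.359 with an estimated correlation). The fatty acid elongases Elovl7 and Elovl6 fell (-1.33 and -0.82), and malic enzyme, Me1, rose by 0.59. Of 36 cornified envelope genes outside the Lce1 cluster 0 rose, 33 did not pass and 3 fell, Ppl (-2.33), Casp14 (-1.57) and Tgm5 (-1.25), without a call of the list (adjusted p = 0.344). Ivl differed by 1.28 (adjusted p = 0.056) and Lor by 0.53 (adjusted p = 0.22). Ivl passed with median centring (adjusted p = 0.033), without the dimmest 25% (adjusted p = 0.039) or dimmer 50% of genes (adjusted p = 0.034) and without TGFβ replicate 1 (1.78, adjusted p = 0.0071), and Lor without TGFβ replicate 2 (0.90, adjusted p = 0.0073). The Casp14 call was lost without untreated replicate 2 (adjusted p = 0.0895) and with an intensity trend and robust variances (adjusted p = 0.060). The Tgm5 call was lost without TGFβ replicate 1 (adjusted p = 0.097) or 2 (adjusted p = 0.080), and its difference was -0.83 without untreated replicate 1.

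Guidance genes of the semaphorin, ephrin and netrin families showed 7 rises, 14 falls and 20 genes that did not pass among 41 measured (adjusted p = 0.0425, and adjusted p = 0.359 with an estimated correlation). Netrin 1, Ntn1, fell by 2.74, Sema3c fell by 1.98 to a mean under 7 and Slit2 fell by 1.53, while Sema4f rose 4.91-fold and Efna2 rose 2.73-fold. Notch ligands, receptors and Hes-Hey genes showed 2 rises, 5 falls and 14 genes that did not pass among 21 measured (adjusted p = 0.34). The ligand Jag1 rose 7.20-fold and the receptor Notch4 rose by 0.58, whereas Jag2 (-1.76), Notch1 (-1.35), Dll1 (-1.14), Nrarp (-0.99) and Notch3 (-0.69) fell. The Notch3 call was lost without TGFβ replicate 1 (adjusted p = 0.069) or 2 (adjusted p = 0.068). Of 22 cadherins 2 rose, Cdh6 and Cdh10, and 3 fell, Cdh13 (-1.73), Cdh2 (-1.42) and Cdh1 (-1.25), without a call of the list (adjusted p = 0.457). The Cdh1 call was lost without untreated replicate 1 (adjusted p = 0.057). Of 19 Wnt ligands 2 rose, Wnt11 by 1.47 and Wnt9a by 0.48, and 2 fell, Wnt10a (-1.79) and Wnt7a (-0.96), without a call of the list (adjusted p = 0.34). The Wnt9a call was lost without untreated replicate 1 (adjusted p = 0.10), untreated replicate 2 (adjusted p = 0.16) or TGFβ replicate 1 (adjusted p = 0.11), and the Wnt7a call without untreated replicate 1 (adjusted p = 0.083) or 2 (adjusted p = 0.098). Of 13 genes of the Lce1 cluster, late cornified envelope proteins of the skin barrier, 7 rose, 0 fell and 6 did not pass (adjusted p = 1.56e-05, and adjusted p = 0.359 with an estimated correlation). Lce1h, already named among the largest rises, is counted in this result. Lce1h (3.66) and Lce1j (2.47) rose, as did Lce1g (2.91) and Lce1i (2.78), whose untreated means of 4.85 and 6.07 lie near background, so that their sizes are not compared. The Lce1k call (0.50) was lost without untreated replicate 1 (adjusted p = 0.070), and the Lce1f call (1.52) without untreated replicate 1 (adjusted p = 0.053) or 2 (adjusted p = 0.059) and with an intensity trend and robust variances (adjusted p = 0.054).

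Epithelial junction genes were less reduced in TGFβ replicate 2, with a mean difference from untreated cells of -0.941 against -1.24 in replicate 1, a gap of 0.297 in which 33 of 39 members were higher. The gap was 0.322 after cyclic loess, and ribosomal protein genes differed by 0.0236. Array scaling is not excluded by this, since the deposited values were already quantile-normalized and cyclic loess could move the gap little. The ribosomal list means in the TGFβ arrays, 12.07 and 12.09, also lay well above the epithelial means of 8.35 and 8.65. Fewer responding cells in replicate 2 lower the genes that rose as well, and their median gap was -0.153 (bootstrap 95% interval -0.181 to -0.107), but mixing gives every gene the same share, and on linear values this share was 15.4% (10.7% to 17.8%) from genes that rose and 6.31% (5.13% to 7.42%) from genes that fell. These intervals do not overlap, but they treat genes of the same arrays as independent, and background limits linear values. The 26 epithelial genes that fell gave 9.60% (6.55% to 13.7%), an interval that overlaps both but is too wide to reconcile them. Only the dependence between genes and the background limit keep a single share from being excluded. A mix beside other differences stays open as well. Replicate 2 also had higher interferon (0.464), amino acid stress (0.271) and protease lists (0.236) and lower DNA replication (-0.271) and mitosis lists (-0.184), the last 2 in 29 of 29 members each, while between untreated replicates 2 and 1 the gap was 0.276 for DNA replication, 0.174 for mitosis and -0.148 for epithelial genes, and no biological explanation was tested.

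The 7 rises among Lce1 genes stood beside 26 falls among epithelial junction genes. A general rise of cornified envelope genes is not seen, since the 11 others with a mean of at least 7 in either group had a median of -0.328 (bootstrap 95% interval -1.25 to 0.0861), although Ivl, Lor, Cnfn (0.056) and Sprr1a (0.086) lay above 0. Cross-hybridization between the Lce1 copies cannot be told apart from separate rises, since the lowest difference over the 6 bright probe sets was 0.498, none fell, and probe sequences were not used. How many Lce1 genes responded may therefore be fewer than 7. An effect of TGFβ on this cluster stays open, with no test beyond the comparison itself.

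Cholesterol synthesis genes were lower together, and the median stayed at -0.688 or further from 0 under 3 other scalings, against -0.705. The deposited values were already quantile-normalized, so further scaling could move a list little and a scaling effect is not excluded. Variation between cultures of a condition may account for part of it, since the gap between the TGFβ replicates in the list mean, 0.46, was 0.614 of the difference between the conditions, -0.749. Between untreated replicates 2 and 1 the gap in this list was only -0.0441. All 20 members were higher in TGFβ replicate 2 than in replicate 1, and the estimated correlation between members was 0.90. An effect of TGFβ itself stays open as well, since both TGFβ arrays lay below the untreated mean, by -0.979 and -0.519.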
